A study of Arabidopsis thaliana with 18 samples.

How the data were processed

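Full rosettes of Col-0 plants were frozen in the growth chamber, 15 rosettes were ground together per sample, and biotin-labelled cRNA from total RNA was hybridised to Affymetrix Arabidopsis arrays, per the labels' protocols. The series has 18 arrays, 3 at each of 6 times, and per its design text the 3 replicate courses were grown separately. The deposited values are signal intensities on a linear scale, 1 per probe set and array, between 0 and 13157, and MAS5 is the tool named in the submitters' processing notes, with its version not given in the sources used here. The values show that each array had been scaled, since the mean after trimming 2% at each end was about 100 on every array. No detection calls were used here, so whether a probe set lay above background could not be judged, and 576 values were listed at 0.

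Groups were taken from the sample titles, which give time and replicate letter. No 2 arrays held identical values and no column of sample values was left out. The 64 control probe sets were left out of the tests. Intensities were analysed as log2(value + 1.1), where 1.1 is the 10th percentile of all deposited values, so log2 differences understate the change of dim probe sets. Array medians on the log2 scale spanned 0.3, below the limit of 0.5 above which quantile normalization would have been used, and the values were kept as deposited. Means and SDs of signals are those of the deposited intensities.

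Genes were taken from a table of the platform's annotation, with symbols updated by Entrez ID through a RefSeq table of the TAIR10.1 assembly, which matched 13436 of the 13513 probe sets with 1 gene. The files name no genome build, and no coordinates are given. Of the 266 genes in 21 lists fixed beforehand (clock, photosynthesis, carbon metabolism, growth, stress, other organs and reference genes), 41 had a named probe set. The lists of nitrate and sulphate assimilation, cell cycle and flower markers had none and were not analysed here, and a list of cytosolic ribosomal proteins was not built because it needed gene descriptions. The remaining 18 lists were tested, many with 1 or 2 members, for which the result is hardly more than that of the gene itself. The reference gene UBC21 carries the symbol PEX4 in the tables, and HPR1 the symbol HPR.

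The models were fitted with limma 3.58.1 in R 4.3.3 to all 18 arrays, with 12 residual degrees of freedom, eBayes with an intensity trend and Benjamini-Hochberg adjustment over 22746 probe sets. Calls had an adjusted p below 0.05. The tests were a moderated F test of 6 time means, a moderated F test of the cosine and sine of time with a period of 24 h, an F test of the departure from that cosine, and 9 contrasts of 2 times. Gene lists were tested with camera, two-sided, with a preset correlation of 0.01, 1 probe set per gene and adjustment over the lists. On simulated data for the 22746 probe sets, the F test recovered 36% of profiles with a peak-to-trough difference of 1 and 89% with 2 on the log2 scale, with 6 false calls beside 125 true ones. The cosine test recovered 59% and 97%, with 8 false calls beside 156 true ones. The simulated profiles were 24 h cosines, placed only in probe sets at or above the median mean. Their noise was independent between arrays, with no likeness of arrays of a series, so these figures need not hold for the real data.

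Named genes followed a rule set before the data were examined. For each comparison 12 h apart, these were the 8 largest differences in each direction among calls with 1 named gene, a mean at the higher time at or above the median probe set, and the same direction in series A, B and C. For neighbouring times the 3 largest in each direction were taken, for the F test the 10 largest ranges, for the cosine the 2 largest amplitudes per 4 h window of peak hour, and every member of the lists could be named. Exceptions are stated where they occur.

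Since the letters mark courses grown separately, the letter pairs arrays across times. The deviations from the time means correlated on average by 0.174 between arrays of series A, 0.161 in series B and 0.328 in series C, and by -0.109 between different letters. The value between letters largely follows from those within series, since deviations from a time mean cancel out over the letters. The lowest value within a series was -0.277, between the arrays labelled 4 h B and 16 h B. As each series has 1 array per time, 2 times could not be tested against each other within a series, but the cosine could be, with 3 residual degrees of freedom, and the series entered as a block in an alternative fit. Other alternatives were quantile normalization, a shift of each array to the same median, no offset with values below 1 set to 1, an offset at the 25th percentile (7.1), leaving out dim probe sets below the 40th percentile of mean signal, eBayes without a trend, a minimum log2 difference of 1, camera with an estimated correlation, and leaving out each series and each array. After seeing the data, 3 were added, leaving out the arrays labelled 4 h B and 16 h B together, testing only lists with at least 3 named members, and fitting the cosine within each series alone.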

Results

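Transcript levels were measured in full rosettes of wild-type Arabidopsis thaliana Col-0 plants aged 5 to 6 weeks, with Affymetrix arrays carrying 22810 probe sets. Rosettes were collected at 6 labelled times, 0, 4, 8, 12, 16 and 20 h, and each time was represented by 3 arrays. The 3 arrays of a time came from 3 courses of plants grown separately, called series A, B and C here after the replicate letters, so each series holds 1 array per time. The labels do not state when the light was switched on, so times are given only as labelled. The median signal of an array lay between 32.2 and 39.9, and the small number of arrays per time limits the precision of every mean. Of the 22746 probe sets tested, 13513 could be assigned to 1 gene, 503 matched several genes and 8730 are unnamed here, so most clock genes of the gene lists have no value here.

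Series C differed from A and B in its controls. The bacterial spike-in bioC had a mean signal of 618 ± 72.8 in series C, against 169.6 ± 11.8 in series A and 165.4 ± 5.78 in series B (SD, n = 6 arrays each). The 3'/5' signal ratio of the ubiquitin control, a sign of RNA quality, was 3.21 ± 0.65 in series C, 1.75 ± 0.09 in series A and 1.65 ± 0.10 in series B. Since every series holds every time, this offset was not aligned with time. A second feature was aligned with time: the arrays labelled 4 h B and 16 h B correlated better with the other series' arrays of the time 12 h away than with those of their own time. The mean correlation of log2 values was 0.945 with the own time and 0.963 with 16 h for the array labelled 4 h B, and 0.946 and 0.967 for the array labelled 16 h B. For every array of the 0, 8, 12 and 20 h groups the own time gave a higher correlation than the time 12 h away, and the other arrays of 4 and 16 h lay close to 0, with -0.0011 for 4 h A as the lowest difference. Those differences include the arrays labelled 4 h B and 16 h B. Between series A and C alone, the correlation was 0.958 for the 4 h arrays and 0.955 for the 16 h arrays. It was 0.937 between 4 h A and 16 h C and 0.935 between 4 h C and 16 h A. Over all 6 times, 10 of the 18 arrays had their highest mean correlation with another time than their own. Among them, the array labelled 8 h B had 0.957 with 8 h and 0.966 with 12 h, and the array labelled 12 h B had 0.959 with 12 h and 0.966 with 8 h, while 8 h C and 12 h A also lay slightly closer to the other of these times. For arrays of series A and C, these means include series B. Between series A and C alone, every array correlated highest with the array of its own time. The margin was small for some, as 8 h C had 0.956 with 8 h A and 0.95 with 12 h A. GI, a component of the circadian clock, also ordered the series B arrays differently at other times. Its signal was 298 at 8 h and 167 at 12 h in series A, 401 and 74.8 in series C, but 120.7 and 411 in series B.

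**Figure D1:**
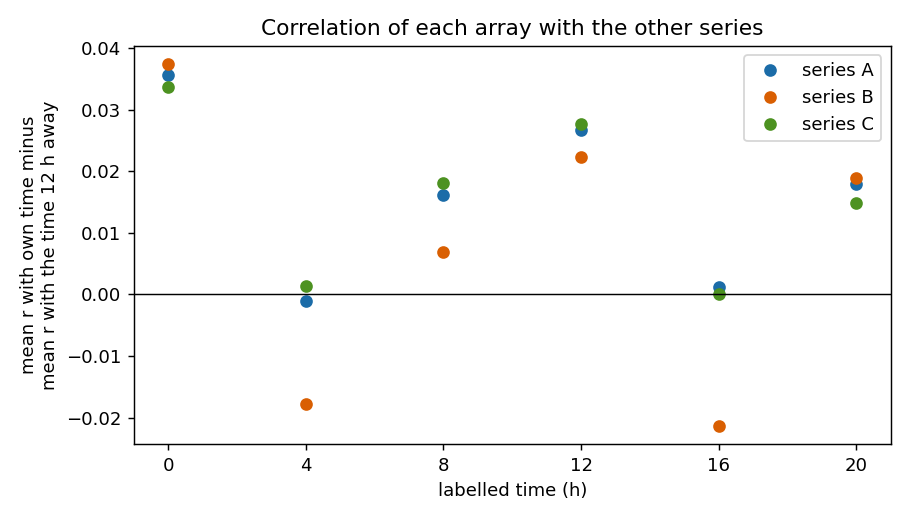
For each of the 18 arrays (points, coloured by series), the mean correlation r of log2 values with the other series' arrays of its own time minus that with the arrays of the time 12 h away, against labelled time in hours. The arrays labelled 4 h B and 16 h B lie clearly below 0, at -0.018 and -0.021, while all arrays of 0, 8, 12 and 20 h lie above 0.

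The first question was which transcripts changed over the course of the day. The largest ranges belonged to genes with a maximum at 8 to 12 h or at 0 h. COR15A (AT2G42540), a cold-regulated chloroplast protein, rose from a mean signal of 41.7 ± 6.1 at 0 h to 3496 ± 962 at 12 h and was back at 148.8 ± 63.2 at 20 h (SD, n = 3), a range of 6.33 on the log2 scale (limma moderated F test, adjusted p = 1.55e-08). Its close relative COR15B had a range of 5.56 (adjusted p = 1.01e-07). The opposite course was seen for AT1G68440, at 893.5 at 0 h and 11.6 at 8 h (range 6.48, adjusted p = 3.87e-06), AT1G49200 (range 5.78) and AT2G41250 (range 5.68). The other members of the 10 largest ranges were AT1G07050, AT1G51090 and AT4G33980, lowest at 0 h, and AT2G15020 and AT1G26790, highest at 0 h.

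The number of probe sets that changed with time was 1486, of which 724 had a single named gene. Of these 1486, the highest mean fell at 0 h for 710, at 8 h for 385 and at 12 h for 294, but at 4 h for 37, at 16 h for 10 and at 20 h for 50. The count was 2565 with series as a block and 2734 without the arrays labelled 4 h B and 16 h B, a setting chosen after seeing the data. It was 172 without series A, 301 without series C, 965 without the 0 h array of series A and 971 without that of series B.

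**Figure D2:**
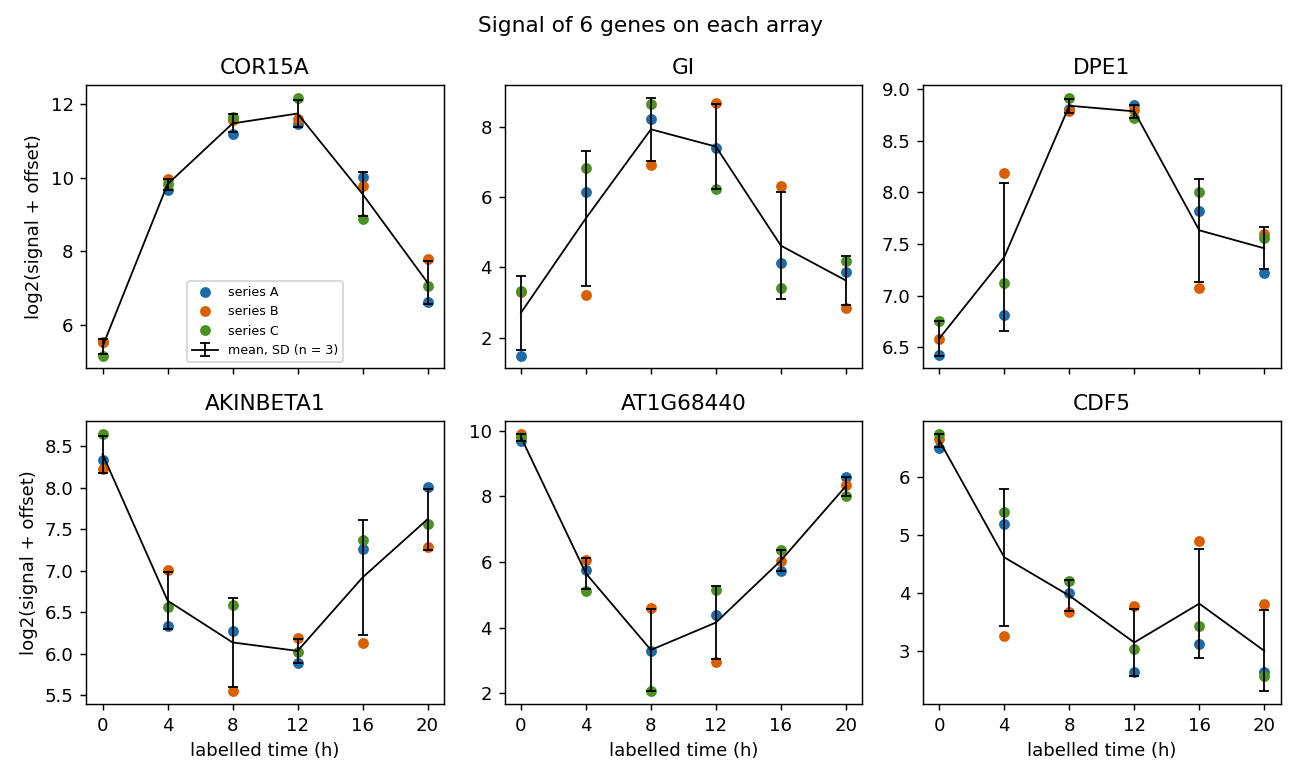
Log2 of signal plus offset for 6 genes on each array against labelled time in hours, with points for the series and a black line for the mean with its SD (n = 3). COR15A, GI and DPE1 are highest at 8 and 12 h, while AKINBETA1, AT1G68440 and CDF5 are highest at 0 h, and the series B points at 4 and 16 h lie apart from the others for GI, CDF5 and DPE1.

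Most of these courses had a component of a cosine with a period of 24 h. COR15A peaked at 10.30 ± 0.27 h with a peak-to-trough difference of 6.17 on the log2 scale, and AT1G07050 at 10.97 ± 0.60 h (6.03). AT1G51090 and AT1G11210 peaked at 9.77 ± 0.45 h and 9.86 ± 0.42 h (SE). Late fitted peaks were found for AT1G68440 at 21.97 ± 0.33 h, AT2G04795 at 21.91 ± 0.29 h, AT1G49200 at 22.07 ± 0.40 h and AT2G15020 at 23.13 ± 0.64 h. All these peak hours belong to the fitted curve and are not measured maxima, and their SE presumes that the course is a cosine. The signal of AT1G68440 was highest at 0 h in each series. It was 828.9, 960.6 and 891 at 0 h in series A, B and C, against 380.5, 326.4 and 254.6 at 20 h. GI peaked at 9.72 ± 0.53 h with all arrays (limma cosine F test, adjusted p = 0.000223), but at 9.47, 11.63 and 7.78 h within series A, B and C alone, a spread wider than this SE. COR15A peaked at 10.42, 10.42 and 10.09 h and AT1G68440 at 22.02, 22.67 and 21.23 h within the same series. In the window centred on 16 h, AT1G65560 alone met the rule for naming, with a peak-to-trough difference of 0.82 (adjusted p = 0.0225), and in that centred on 4 h no gene did.

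The number of probe sets with a 24 h cosine component was 2844 by the limma F test, of which 1410 also passed the test over 6 time means, and 5 departed from the cosine. So few departures do not show that a cosine described the others well, since the power of that test was not examined. CDF5 had a range of 3.63 and a fitted peak-to-trough difference of 2.49, yet no call for departure (limma F test, adjusted p = 0.364). Of the 2844, 888 had their fitted peak in the 4 h window around 0 h and 500 in that around 8 h. The windows around 12 h and 20 h held 882 and 562, but those around 4 h and 16 h held 9 and 3. A fitted peak need not be the time of the highest mean, which was 20 h for only 50 of the probe sets that changed with time. In the 12 arrays of series A and C, 225 peaked around 4 h and 222 around 16 h. Leaving out only the arrays labelled 4 h B and 16 h B, 184 and 178 did, so the near absence of these peaks rests on those 2 arrays. They were still fewer than in the windows around 0, 8, 12 and 20 h, which then held 912, 812, 984 and 947. Fitted within a series alone, a setting chosen after seeing the data, the limma count was 851 in series A, 0 in series B (3058 at an unadjusted p below 0.05) and 122 in series C. The count of 2844 was 738 without series A and 1856 without series C, and a single 24 h course cannot show that a profile repeats.

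**Figure D3:**
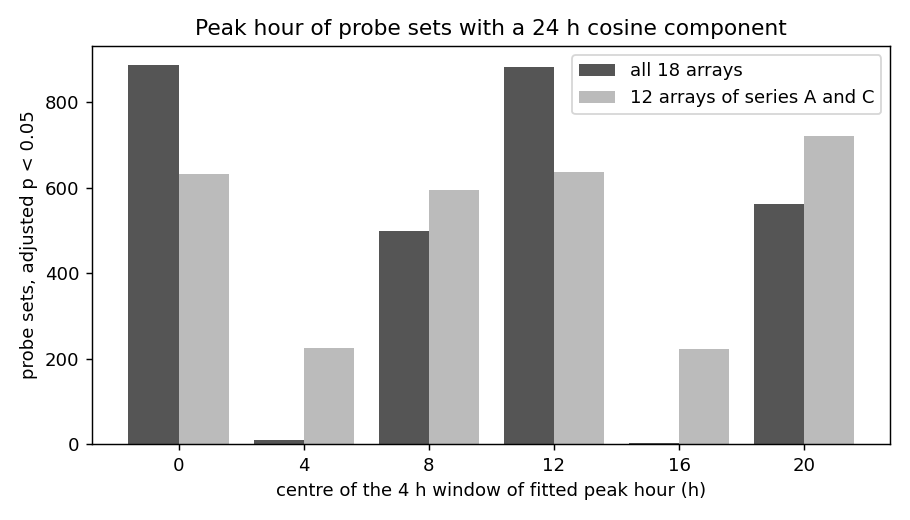
Number of probe sets with a 24 h cosine component (limma, adjusted p below 0.05) by 4 h window of fitted peak hour, from all 18 arrays (dark bars) and from the 12 arrays of series A and C (light bars). With all arrays the windows around 4 and 16 h hold 9 and 3 probe sets, and without series B they hold 225 and 222.

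Between 12 h and 0 h, genes of the cold and dehydration list stood far higher at 12 h. COR15A was higher by 6.33 ± 0.30 on the log2 scale (SE, limma adjusted p = 4.36e-09), COR15B by 5.54 ± 0.34 (adjusted p = 4.59e-08) and COR47, a dehydrin, by 1.62 ± 0.34 (adjusted p = 0.00484). Both measured starch degradation genes were higher, DPE1, the plastid disproportionating enzyme, by 2.2 ± 0.28 and PWD, phosphoglucan water dikinase, by 1.74 ± 0.46. APL3, a large subunit of ADP-glucose pyrophosphorylase, was higher by 1.72 ± 0.37, PORB, a protochlorophyllide oxidoreductase, by 1.51 ± 0.33 and GI by 4.74 ± 0.91. Lower at 12 h were both measured starvation genes, as AKINBETA1, a subunit of the SnRK1 kinase, fell by 2.37 and MCCA, an enzyme of leucine breakdown, fell by 1.16, together with CDF5, a DOF transcription factor, which fell by 3.49. GLYK, glycerate kinase of photorespiration, fell by 0.43 (adjusted p = 0.0466, and 0.145 with each array shifted to the same median).

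Among the genes with the largest differences, AT1G07050 (6.49), AT4G33980 (5.70), AT2G23910 (5.32), AT1G51090 (5.26), AT4G16146 (5.20) and AT2G39920 (5.16) were higher at 12 h beside COR15A and COR15B. The largest decreases were those of AT2G15020 (-6.19), AT1G49200 (-5.78), AT1G68440 (-5.65), AT2G20670 (-5.28), AT1G26790 (-5.10), AT1G64500 (-4.78), AT2G41250 (-4.74) and AT3G15310 (-4.47). All 16 differed in the same direction in each series, as the rule for naming required. Several of them sit near the floor at their lower time, such as AT4G33980 with a mean signal of 0.567 at 0 h, and their log2 differences depend on the offset.

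Overall calls between 12 h and 0 h numbered 2473 probe sets, 1235 higher and 1238 lower at 12 h, and 1240 of them had a single named gene. With series as a block the count was 3888, and it was 557 without series A and 1090 without series C.

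Of the 18 gene lists with a named member, 5 passed limma's camera test between 12 h and 0 h. Counts of members, here and below, are of measured genes only. Those were 3 of 10 genes for cold and dehydration, 2 of 19 for starch degradation, 3 of 16 for starch synthesis and 2 of 17 for sugar starvation. Cold and dehydration was shifted upward with 3 of 3 members called (adjusted p = 1.38e-07), as were starch degradation with 2 of 2 (adjusted p = 0.00696) and starch synthesis with 1 of 3 (adjusted p = 0.0241). Sugar starvation was shifted downward with 2 of 2 (adjusted p = 0.00117), and so was the photoperiod list, of which CDF5 is the sole measured member (adjusted p = 0.0268). With an estimated correlation, cold and dehydration kept its call (adjusted p = 0.00469), while the adjusted p with an estimated correlation was 0.133 for starch degradation, 0.121 for starch synthesis, 0.112 for sugar starvation and 0.121 for the photoperiod list. With series as a block 3 lists passed, and without dim probe sets 3 did. Which lists these were is not given here. Without the arrays labelled 4 h B and 16 h B, the same 5 lists passed and evening clock, with GI alone, was a sixth (adjusted p = 0.0344). In that fit the adjusted p with an estimated correlation was 0.0251 for cold and dehydration, 0.0492 for starch degradation and 0.0899 for evening clock. It was 0.067 for starch synthesis, 0.067 for sugar starvation and 0.067 for the photoperiod list.

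The lists of the light-harvesting antenna and the Calvin-Benson cycle gave no call between 12 h and 0 h. Only 3 of 18 antenna genes and 3 of 20 Calvin-Benson genes were measured, so the other genes of these lists are not covered. LHCB4.1, LHCB4.2 and LHCB4.3 of the antenna differed by 0.04 ± 0.35, -0.90 ± 0.59 and 0.02 ± 0.41, and SBPASE, PRK and RCA of the Calvin-Benson cycle by -0.23 ± 0.24, -0.16 ± 0.28 and -0.39 ± 0.42. The camera adjusted p was 0.804 for the antenna, whose median and mean difference had opposite signs, and 0.589 for the Calvin-Benson cycle. Other lists without a call with all arrays were evening clock, with GI alone (adjusted p = 0.0739), morning clock, with RVE6 alone (adjusted p = 0.815), sucrose synthesis and export (adjusted p = 0.509), photorespiration (adjusted p = 0.464), phenylpropanoid and flavonoid, with DFR alone (adjusted p = 0.589), chlorophyll synthesis (adjusted p = 0.58) and expansion growth (adjusted p = 0.358). The heat shock gene HSP17.6C (adjusted p = 0.589), the defence gene PDF1.2 (adjusted p = 0.815), the root markers PYK10 and EXPA7 (adjusted p = 0.815) and the 5 reference genes (adjusted p = 0.815) gave none either. For the root markers the median difference (0.13) and the test's direction had opposite signs, as they had for the reference genes (-0.03). Among the reference genes, SAND differed by 0.44 ± 0.13 in its own test (limma adjusted p = 0.0415, and 0.0877 with each array shifted to the same median).

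Over the whole course, all 3 measured cold genes, both starch degradation genes, both starvation genes, GI and CDF5 passed the F test over all probe sets, and the same numbers passed when adjusted over the list alone. For starch synthesis 1 of 3 passed over all probe sets and 3 of 3 when adjusted over the list alone. For sucrose synthesis and export the numbers were 0 and 2 of 3, with SWEET11 and the sucrose phosphate synthase SPS4F (listed as ATSPS4F) passing when adjusted over the list alone. For photorespiration they were 0 and 1 of 3, with GLYK passing, and for chlorophyll synthesis 1 of 3 in both, with PORB passing. Without series A, and likewise without series C, COR15A and COR15B alone of the 11 list genes called over all probe sets kept their call. PWD (adjusted p = 0.0442) lost it also with quantile normalization (0.0609), with equal medians (0.056), with the block (0.0557), with no offset, with the larger offset and without the variance trend. Without the arrays labelled 4 h B and 16 h B, LHCB4.2 (adjusted p = 0.0085), SBE2.2 (adjusted p = 0.0312), SPS4F (adjusted p = 0.037), SWEET11 (adjusted p = 0.00189) and GLYK (adjusted p = 0.0432) passed in addition.

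Between 20 h and 8 h the same cold genes were low at 20 h. COR15A fell by 4.32, COR15B fell by 4.32 and COR47 fell by 1.60 on the log2 scale (limma adjusted p = 1.63e-06, 2.49e-06 and 0.0145). GI fell by 4.31 (adjusted p = 0.0139) and DPE1 fell by 1.38 (adjusted p = 0.0101). The adjusted p of GI was 0.378 without series A, 0.15 without series C, 0.0574 and 0.0717 without the 8 h arrays of series A and C, and 0.0504 and 0.0672 without the 20 h arrays of series A and B. AKINBETA1 was higher at 20 h by 1.48 ± 0.31 (adjusted p = 0.0137) and SPS4F by 1.62 ± 0.37 (SE, adjusted p = 0.0237). The other largest decreases were those of AT1G11210 (-5.04), AT1G56300 (-4.45), AT1G51090 (-4.33), AT1G20030 (-4.07) and AT4G30660 (-3.47). The 8 largest increases were those of AT1G68440 (4.99), AT5G26200 (3.90), AT1G49200 (3.88), AT4G21870 (3.58), AT3G15310 (3.52), AT2G04795 (3.46), AT1G64500 (3.45) and AT2G28200 (3.34). AT5G26200 lost its call without series A, B or C (limma adjusted p = 0.104, 0.0835 and 0.0529). AT4G21870, AT2G28200, AT1G51090 and AT1G20030 lost theirs without series A and without series C. AT1G49200 and AT1G64500 did so without series A, and AT1G11210 without series C.

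In this comparison 742 probe sets passed, 413 higher and 329 lower at 20 h. Of the probe sets called higher at 12 h than at 0 h, 295 were also called lower at 20 h than at 8 h, against 17.9 for independent lists, and 383 were called in the reverse directions, against 22.5. No probe set was called higher in both or lower in both. The comparisons share no array, although they share the estimate of the spread. The count was 1560 with series as a block and 1283 without the arrays labelled 4 h B and 16 h B, which enter through the spread. It was 47 without series A, 104 without series C, 407 and 352 without the 8 h arrays of series A and C, and 299, 484 and 448 without the 20 h arrays of series A, B and C.

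Here 6 lists passed the camera test. Shifted downward at 20 h were cold and dehydration with 3 of 3 members called (adjusted p = 9.8e-10), starch degradation with 1 of 2 (adjusted p = 0.0206), as PWD differed by -0.87 ± 0.46 (adjusted p = 0.413), and evening clock, with GI alone (adjusted p = 0.0256). Shifted upward were sugar starvation with 1 of 2 (adjusted p = 0.0069), as MCCA differed by 0.69 ± 0.19 (adjusted p = 0.0628), sucrose synthesis and export (adjusted p = 0.017) and photorespiration (adjusted p = 0.0206), although no single photorespiration gene was called and 1 of 3 genes was in the sucrose list. With an estimated correlation cold and dehydration kept its call (adjusted p = 0.00154). The adjusted p with an estimated correlation was 0.179 for starch degradation, 0.145 for evening clock, 0.145 for sugar starvation, 0.155 for the sucrose list and 0.164 for photorespiration. Without the arrays labelled 4 h B and 16 h B the same 6 lists passed, and cold and dehydration alone kept its call with an estimated correlation (adjusted p = 0.0107). The number of lists was 2 without series C, 2 without dim probe sets, and 3 without the 8 h array of series A or the 20 h array of series B.

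Between 16 h and 4 h, as labelled, limma called no probe set, and 391 had an unadjusted p below 0.05. No list passed the camera test, where starch synthesis had the smallest adjusted p (0.377), and chlorophyll synthesis had a median difference of -0.06 against an upward direction of the test. COR15A had a mean signal of 789.6 ± 288 at 16 h and 905 ± 90.8 at 4 h, DPE1 204.9 ± 63.9 and 179.9 ± 96.2, and GI 34.9 ± 38.1 and 63.6 ± 52.5 (SD, n = 3). The GI signal was 70.0 and 112.6 on the 4 h arrays of series A and C and 8.2 on the array labelled 4 h B, and 16.4 and 9.5 on the 16 h arrays of series A and C and 78.7 on the array labelled 16 h B. The count was 0 also with series as a block and without the variance trend. Without the arrays labelled 4 h B and 16 h B it was 749 probe sets, 358 higher and 391 lower at 16 h, and without series B it was 843. Without both arrays, starch degradation was the 1 list that passed (adjusted p = 0.000432, and adjusted p = 0.119 with an estimated correlation). The number of lists was 1 without the array labelled 4 h B alone and 3 without series B, for which no correlation was estimated.

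In the fit without those 2 arrays, which was chosen after seeing the data and leaves 2 arrays at each of both times, COR27, a cold-regulated gene linked to the clock, had the largest positive difference, 5.38 ± 0.31 (limma adjusted p = 4.27e-07). It was followed by AT2G23910 (4.41) and AT4G33980 (4.40). The largest negative differences were those of AT1G13650 (-5.66) and AT5G67390 (-5.55). With all 18 arrays the difference for COR27 was 1.88 ± 1.24 and for AT1G13650 it was -1.35 ± 1.61. The 2 arrays had been left out for resembling the other of these same 2 times. The calls and adjusted p values of 16 h against 4 h in that fit therefore follow in part from the choice.

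The comparisons of neighbouring times placed most changes between 0 h and 4 h. From 0 h to 4 h COR15A rose by 4.41 ± 0.30, AT2G03310 by 3.85 ± 0.38 and AT2G39920 by 3.75 ± 0.45, while AT1G26790 fell by 5.41, AT1G68440 fell by 4.15 and AT1G49200 fell by 4.06. From 4 h to 8 h AT1G11210 (3.73 ± 0.69), AT1G16850 (3.13 ± 0.60) and AT1G56300 (2.97 ± 0.43) rose, and AT1G64500 (-2.14 ± 0.40), AT3G15310 (-2.04 ± 0.40) and SWEET2, a sugar transporter (-1.53 ± 0.26), fell. From 12 h to 16 h BZIP61, a bZIP transcription factor (2.54 ± 0.48), AT4G21870 (2.42 ± 0.48) and AT2G04795 (1.85 ± 0.31) rose, and AT1G11210 (-3.44 ± 0.69), COR15B (-2.37 ± 0.34) and AT1G19960 (-2.34 ± 0.33) fell. From 16 h to 20 h AT4G15430 rose by 1.89 ± 0.25 and COR15A fell by 2.41, and the other 2 calls, unnamed probe sets listed after their values were seen, were 250099_at (3.56 ± 0.44) and 260412_at (-2.35 ± 0.28). At 0 h against 20 h AT1G55960 (3.95 ± 0.75), CDF5 (3.63 ± 0.56) and AT1G54740 (1.69 ± 0.31) were higher, and AT2G39920 (-3.39 ± 0.45), AT3G62550 (-3.16 ± 0.61) and AT2G03310 (-3.06 ± 0.38) were lower. Of these, AT4G21870 from 12 h to 16 h and AT1G55960 and AT3G62550 at 0 h against 20 h lost their call with quantile normalization, with equal medians, with no offset and without the variance trend. Calls of BZIP61, AT1G64500, AT3G15310, AT1G11210, AT1G16850, AT1G54740, SWEET2 and AT2G04795 were lost under some of these settings.

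**Figure D4:**
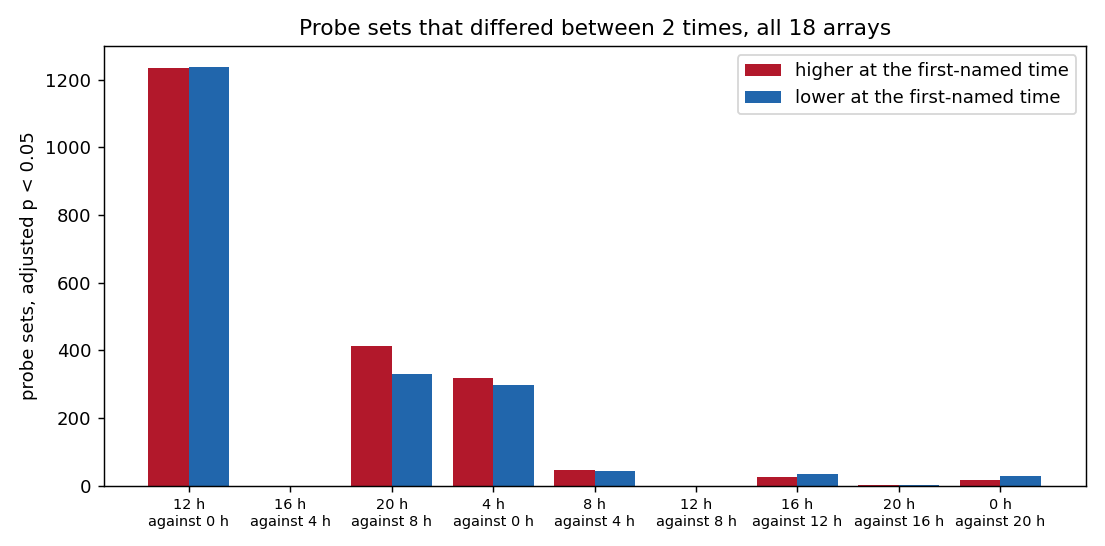
Number of probe sets with a limma adjusted p below 0.05 that were higher (red) or lower (blue) at the first-named time, for each of 9 comparisons of 2 times with all 18 arrays as labelled. The bars reach 1235 and 1238 for 12 h against 0 h and are absent for 16 h against 4 h and 12 h against 8 h.

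The limma calls numbered 617 for 4 h against 0 h (320 higher, 297 lower), 89 for 8 h against 4 h (46 and 43), 62 for 16 h against 12 h (26 and 36), 4 for 20 h against 16 h (2 and 2) and 45 for 0 h against 20 h (17 and 28). For 12 h against 8 h the count was 0, with 265 at an unadjusted p below 0.05, 0 with series as a block, and 124 without series B. With series as a block the other counts, in the order given, were 1460, 179, 156, 8 and 96. Without the arrays labelled 4 h B and 16 h B they were 1372, 486, 286, 37 and 196. Without series A they were 68, 0, 1, 0 and 3, without series B 1082, 481, 258, 53 and 82, and without series C 48, 0, 0, 0 and 1. The median log2 difference of all probe sets was 0.12 for 4 h against 0 h. With each array shifted to the same median, the calls there were 169 higher and 395 lower, those for 8 h against 4 h were 40 and 20, those for 16 h against 12 h were 13 and 31, and those for 0 h against 20 h were 15 and 14. With quantile normalization, those for 20 h against 16 h were 3 and 2.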

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

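The settings without the arrays labelled 4 h B and 16 h B, with lists of at least 3 members and with the cosine within each series alone were chosen after the results were seen. With series as a block, the count of probe sets that changed with time was 2565 (1486 without the block), and the calls were 3888 for 12 h against 0 h, 1560 for 20 h against 8 h, 1460 for 4 h against 0 h, 179 for 8 h against 4 h, 156 for 16 h against 12 h, 8 for 20 h against 16 h and 96 for 0 h against 20 h, with 3 lists passing for 12 h against 0 h. The block moved no other count by over 1.5 times. Without the arrays labelled 4 h B and 16 h B, the count over time was 2734, and the contrasts gave 749 for 16 h against 4 h (0 with all arrays), 1283 for 20 h against 8 h, 1372 for 4 h against 0 h, 486 for 8 h against 4 h, 286 for 16 h against 12 h, 37 for 20 h against 16 h and 196 for 0 h against 20 h, with 1 list for 16 h against 4 h. Without a variance trend, 20 h against 8 h gave 447, 4 h against 0 h 356, 8 h against 4 h 29, 16 h against 12 h 18 and 0 h against 20 h 16. The probe sets with a 24 h cosine component numbered 851, 0 and 122 within series A, B and C alone, with 6 arrays each. With no offset, 8 h against 4 h gave 50 and 16 h against 12 h 41, and with equal medians 0 h against 20 h gave 29. Requiring a log2 difference of at least 1 left 1434 for 12 h against 0 h, 450 for 20 h against 8 h and 374 for 4 h against 0 h. The lists passing for 12 h against 0 h and 20 h against 8 h numbered 1 and 1 with an estimated correlation, 3 and 2 without dim probe sets, and 2 and 3 among lists with at least 3 members. The cause of these shifts was not tested, except that a limit on size can only remove calls.

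Leaving out each series or array in turn gave 172 to 2087 probe sets that changed with time, 738 to 3476 with a cosine component, and 557 to 2729 for 12 h against 0 h, 0 to 843 for 16 h against 4 h, 47 to 965 for 20 h against 8 h, 48 to 1082 for 4 h against 0 h, 0 to 481 for 8 h against 4 h, 0 to 124 for 12 h against 8 h, 0 to 258 for 16 h against 12 h, 0 to 53 for 20 h against 16 h and 1 to 82 for 0 h against 20 h. The lists passing numbered 4 to 6 for 12 h against 0 h, 0 to 3 for 16 h against 4 h and 2 to 7 for 20 h against 8 h. For 4 h against 0 h the count was 68 without series A, 1082 without B and 48 without C, 294, 285 and 284 without the 0 h arrays of A, B and C, and 312, 949 and 209 without those of 4 h. For 8 h against 4 h it was 0 without series A or C and 481 without B, 1, 208 and 25 without the 4 h arrays of A, B and C, 20 and 17 without the 8 h arrays of A and C, and 154 without the array labelled 16 h B. For 16 h against 12 h it was 1, 258 and 0 without series A, B and C, 22, 39 and 28 without the 12 h arrays of A, B and C, 20 without 16 h C, 107 without 4 h B, 38 and 41 without 0 h A and C, and 41 without 8 h A or C. For 20 h against 16 h it was 0, 53 and 0 without series A, B and C. For 0 h against 20 h it was 3, 82 and 1 without series A, B and C, 23, 7 and 9 without the 0 h arrays, 27, 9 and 6 without those of 20 h, 24 without 4 h C and 28 without 12 h A.

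Of 118 values of named genes, 88 were past the threshold. Of the 118, 58 were differences between 2 times, none of which changed direction under any setting listed here, and 60 were ranges or amplitudes, which have no direction. The differences had been named for the same direction in series A, B and C, so leaving out a series could not have reversed them. Without the variance trend 15 lost their call, with no offset 13, with equal medians 7, with quantile normalization 6, with the larger offset 4, with the block 2, without series A 49, without series B 5 and without series C 48. Calls gained were F tests of list genes, 1 each with quantile normalization, no offset and the block (GLYK), 4 without series B (LHCB4.2, LHCB4.3, SPS4F, SWEET11) and 5 without the arrays labelled 4 h B and 16 h B (LHCB4.2, SBE2.2, SPS4F, SWEET11, GLYK), where 1 was lost.

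Calls of AT4G21870 (16 h against 12 h), AT1G55960 and AT3G62550 (0 h against 20 h) were lost with quantile normalization, equal medians, no offset and no trend, and so was the F test of PWD, which the block and the larger offset ended too. Other losses with at least 1 of these 4 settings were BZIP61, AT1G64500, AT3G15310, AT1G11210, AT1G16850, AT1G54740, SWEET2 and AT2G04795 at neighbouring times, and the F tests of AT2G15020 and APL3. Both without series A and without series C, the losses included AT4G33980, AT2G23910 and AT2G15020 for 12 h against 0 h, AT5G26200, AT4G21870, AT2G28200, AT1G51090, GI and AT1G20030 for 20 h against 8 h, the cosine of AT1G65560, and the F tests of 9 list genes. AT1G26790 for 12 h against 0 h was lost without A, and AT1G07050 and AT2G20670 without C. Leaving out 1 array ended 1 to 13 calls, among them AT2G23910 for 12 h against 0 h without 12 h A or C, AT4G15430 without 20 h A or B, CDF5 for 0 h against 20 h without 0 h B, 0 h C, 20 h A or 20 h C, and AT1G65560 without 4 h B or C. Signal over background could not be used to judge dim probe sets.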

Other observations

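The test of the correlations of the arrays labelled 4 h B and 16 h B, the count of splits for 16 h against 4 h and the reorderings of times within each series were chosen only after the result was seen. Gene families were grouped by the stem of their symbols, with at least 8 named genes each, after the names but before their test results were seen, and 32 families and plastid groups were tested with limma's camera. The members named here were chosen after their values were seen. Each one in this paragraph kept its direction and its call with quantile normalization and with equal medians, while the plastid genes named below lost their calls with equal medians. Of the glutathione transferases, GSTU18 had its fitted peak at 22.50 ± 0.46 h and fell by 1.34 on the log2 scale between 0 h and 12 h. GSTU20 and GSTU26 rose by 1.26 and 1.18. Of the glycosyltransferases, UGT74D1 and UGT76C2 fell by 2.09 and 1.87, while UGT84A3, UGT85A5 and UGT80B1 rose by 2.25, 2.14 and 1.45. The sugar transporter SWEET2 fell by 3.06 (limma adjusted p = 1.2e-06), and the autophagy genes ATG8E and ATG8F fell by 2.12 and 0.88, as did the ubiquitin ligase PUB22, which fell by 2.66. None of these families passed camera between 12 h and 0 h (adjusted p = 0.936 for GSTU, 0.852 for UGT and 0.202 for ATG).

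The list of 69 genes encoded in the plastid genome was shifted downward at 12 h against 0 h in the camera test with the preset correlation, with a median log2 difference of -0.41 (adjusted p = 0.00173, and adjusted p = 0.934 with an estimated correlation). The direction of the list was the same with quantile normalization and with equal medians. Its 27 photosynthesis genes, tested as a list of their own, were shifted downward with a camera adjusted p of 0.0697. This was 0.0476 with quantile normalization, 0.0417 with equal medians and 0.934 with an estimated correlation. Of the 69 members 2 were called, rps18 at -0.86 ± 0.25 and rpl33 at -0.79 ± 0.24 (limma adjusted p = 0.0355 and 0.0415). With equal medians their adjusted p was 0.0741 and 0.0526, and no member was called. Among unnamed probe sets, chosen after their values were seen, 266719_at went from a mean signal of 898.6 at 0 h to 3.03 at 12 h, and 267364_at from 2.9 to 416.9.

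For the absence of calls between 16 h and 4 h, several explanations were examined. Low quality of the arrays labelled 4 h B and 16 h B was judged by their correlations. The lower of their highest correlations with series A was 0.973. The lowest correlation between series A and B arrays of the same time at 0, 8, 12 and 20 h was 0.965. That set a highest value over all times against a lowest value at matched times, which favours the outcome seen. Compared alike, the highest correlation with series A was 0.973 for the array labelled 4 h B (with 16 h A). For the array labelled 16 h B it was 0.979 (with 4 h A). For 0 h B, 8 h B, 12 h B and 20 h B it was 0.98, 0.98, 0.974 and 0.969. This argues against a low quality that lowers all correlations of the 2 arrays, though the comparison was made after the result was seen. With the series A array of their own time, the 2 arrays had 0.955 and 0.956. A shift of all of series B by 12 h is argued against. When differences in a series were predicted from a cosine fitted to the other times of the other series, the correlation in series B was 0.739 for 0 h minus 12 h and 0.793 for 8 h minus 20 h across the 1120 and 1749 probe sets with a called cosine in those arrays, and 0.419 and 0.409 across all probe sets. Exchanged labels of both arrays remain open as a hypothesis: for 4 h minus 16 h the correlation across such probe sets was -0.562 in series B, 0.394 in series A and 0.136 in series C, the last short of the 0.2 set beforehand, and across all probe sets it was -0.243, 0.144 and 0.125, while the share of such probe sets with the predicted sign was 42.5%, 51% and 45.4%, so that by sign series A and C were hardly better predicted than series B. The values of series A and C rest on fits that include the 8 h and 12 h arrays of series B, themselves in doubt, probe sets are not independent replicates, and a real difference of series B at these times was not tested.

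Among other splits of the 6 arrays of 4 h and 16 h, the one that exchanges the arrays labelled 4 h B and 16 h B called 1564 probe sets, against 0 as labelled. This points to a structure of the samples, but it largely restates the correlations of these 2 arrays (0.945 and 0.946 with the own time, 0.963 and 0.967 with the time 12 h away) and gives no separate support for exchanged labels. For 12 h against 8 h, the split that exchanges the 8 h and 12 h arrays of series B gave 238, against 0 as labelled, and the count without series B was 124. Both splits part every series between the sides, as the real split does, and no split that parts fewer series called any probe set. Since both real counts were 0, all 10 of the 10 splits necessarily gave as many, which carries no information. With series as a block, both counts as labelled were 0. The labels were kept throughout, and these splits were not used for any value of a gene.

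For the changes over 6 times, the 100 splits of the 18 arrays that ignored the series included 1, the real one, that reached 1486 calls for the F test (highest other 144) or 2844 for the cosine (highest other 0). Those splits mix arrays of a series within a group, unlike the real groups. Among 100 orders of the times within each series, which keep 1 array of each series per group, the real order was again the only 1 to reach these counts, and the highest others were 701 and 1473. This argues against chance for the total counts, but does not show how many single calls arose by chance. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Among those, the real split was the only 1 of 10 to reach its count of 2473 for 12 h against 0 h, 742 for 20 h against 8 h, 617 for 4 h against 0 h, 89 for 8 h against 4 h, 62 for 16 h against 12 h, 4 for 20 h against 16 h and 45 for 0 h against 20 h, and the highest other split gave 0 in each. The lists passing camera numbered 5 for 12 h against 0 h (highest other 1) and 6 for 20 h against 8 h (highest other 2), each in 1 of 10 splits, and 0 for 16 h against 4 h (highest other 2).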
